A study of Mus musculus with 4 samples.

How the data were processed

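KAP1 ChIP-seq was performed on 2 samples of regulatory T cells from mouse spleen, with 2 input samples made without antibody. Per the labels' protocols, chromatin was sonicated, libraries were prepared with a DNA SMART ChIP-Seq kit and fragments of 150 to 400 bp were selected. Per the submitters' processing notes, the tools included Bowtie2 2.2.9, Picard 2.1.1 and MACS2 2.2.1, and the genome build was mm10. The settings of these tools, the control used for each list, the calling threshold and any filter are not given in the sources used here. Each KAP1 sample has 1 deposited list of peak summits, so the replicates were not pooled. The input samples have no list of their own and were not analysed here.

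The deposited lists give each summit a chromosome, a position and a score that is the −log10 of a p-value or a q-value, as MACS writes it. The lists do not say which of these the authors chose. Scores were used only to rank, filter or describe summits within a list. Read depth is not recorded in the lists, so the precision that depth gives is unknown. Positions are given 1-based on mm10.

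Genes were taken from an NCBI RefSeq gene table of GRCm38.p6, whose chromosome coordinates are those of mm10. It held 49980 genes with a position, of which 21900 are protein-coding. The table gives the lowest and highest coordinate of each gene, without strand, transcripts or exons, and no genome sequence was used. The planned promoter window around transcript starts was therefore replaced by a window of 1000 bp around either end of a gene, a change made once the gene table was seen. A gene body was the rest of the gene, for the 19301 coding genes long enough to have one. The planned tests of the last exon of zinc finger genes, of exons and introns, and of base composition and sequence motifs at summits were not run.

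A shared summit was a replicate 1 summit with a replicate 2 summit within 200 bp. The count was compared with 1000 circular shifts of the replicate 1 summits within their chromosomes. Chromosome extents were taken from the summits and genes. The location of summits was compared with 1000 draws of random positions, with the same number per chromosome. The plan left runs of unknown bases out of these draws, which was not done without a genome sequence. Summits on mitochondrial DNA and on unplaced contigs were left out of the location comparison. Shares are given with Wilson 95% intervals, which cover counting error only.

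The 16 gene lists were 11 lists of named genes (regulatory T cell signature, conventional T cell, T cell identity, cell cycle, amino acid transport and mTORC1, KAP1 partners, imprinted genes, and markers of B cells, myeloid cells, erythroid cells and neurons) and 5 families defined by gene name (ribosomal protein, Zfp with a number, olfactory receptor, histone, Hox). Of 264 listed names, Ahsp was not found in the gene table, and Fam208a and Tasor are names of 1 gene. A gene was bound when a shared summit lay at an end or in its body. Each list was compared with all other coding genes (all other genes for imprinted genes) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 16 lists and a threshold of 0.05. For gene bodies, each list was also set against 10000 random lists matched on gene length. The same comparison at gene ends was added after the data were seen. Genes and summits are not independent replicates, so these tests compare genes within 2 libraries and not conditions. With 2 samples of 1 group, no test between samples was made.

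The named genes were fixed by rule. They are the nearest coding genes of the 10 shared summits with the highest mean percentile rank of the 2 scores, the up to 4 highest-ranking members of each list with a shared summit at an end, and Foxp3, Trim28, Il2ra, Ctla4, Ikzf2 and Slc1a5 in every case. Where the rule used transcript starts, gene ends were used. The sample groups, the 16 gene lists, the tests, the alternatives and this rule were fixed before the data were examined. The exceptions are that gene ends stand for promoters throughout, the random positions described above and what is named below as added.

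The alternatives were shared distances of 50 and 500 bp, summits in the upper part of the scores of their own list (at or above its median, ties kept), replicate 2 reduced to its 8862 highest scores, the numbered chromosomes and X only, each replicate's own list, gene ends of 500 and 2500 bp, genes with 5000 bp added on both sides, summits within 1000 bp merged, and chance positions drawn from the same location classes. Added after the data were seen were length-matched lists at gene ends, the omission of genes on X, Y and mitochondrial DNA, a count of summits within 20 kb of genes, and 11 further gene lists.

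The computations were tested on simulated data. With 70% of the 8862 summits placed at a summit of the longer list, 70.3% were found to be shared, and 1.19% after shifts. For gene ends over the 21900 coding genes, 76.2% of lists with a raised share were called and 0% of unchanged lists. The simulated lists were all of the same size with the same raised share. This rate therefore does not carry over to shorter lists or smaller differences. For gene bodies over the same genes, Fisher's exact test called 100% of lists of long genes made without an effect, while 0% lay outside the central 95% of length-matched lists, where chance gives 5%. For location, 8000 uniform positions gave a 1.09-fold share at gene ends. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.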

Results

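KAP1, the product of the Trim28 gene, is a corepressor that KRAB zinc finger proteins bring to DNA. Its positions on chromatin were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse regulatory T cells, the Foxp3-expressing CD4 T cells that restrain immune responses. The cells came from the spleen of C57BL/6 mice and had been sorted and then expanded in culture for 2 weeks. The series holds 2 samples precipitated with an antibody against KAP1 and 2 input samples made without antibody. Each KAP1 sample has 1 list of peak summits, the positions of highest enrichment within each peak. The input samples were not analysed here. Replicate 1 has 8862 summits and replicate 2 has 79515, which is 8.97 times as many. The read depth behind either list is unknown. The labels do not say whether the replicates came from separate cultures or animals, so their differences may be technical.

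Each summit carries the peak caller's score, the −log10 of a p-value or q-value. The authors' scores were used only to rank, filter or describe summits within a list. The median score was 7.25 in replicate 1, with a range from 1.32 to 146.6, and 8.39 in replicate 2, with a range from 2.07 to 153.6. The numbered chromosomes held 8778 of the replicate 1 summits and 78980 of the replicate 2 summits. Chromosome X held 68 in replicate 1 and 451 in replicate 2. The median spacing between neighbouring summits was 48539 bp in replicate 1 and 16671 bp in replicate 2.

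Whether both samples placed KAP1 at the same sites was addressed by pairing summits across the lists. Most sites of the shorter list were found again in the longer one. A replicate 2 summit lay within 200 bp of 7720 of the 8862 replicate 1 summits, or 87.1% (Wilson 95% interval 86.4 to 87.8%). The median distance between paired summits was 6 bp, and 880 pairs fell on the same base. From the other side, 7719 of the 79515 replicate 2 summits had a replicate 1 partner, or 9.71% (9.5 to 9.92%). When the replicate 1 summits were shifted along their chromosomes 1000 times, a mean of 118.6 (SD 10.9, maximum 153) lay near a replicate 2 summit, so the observed count was 65.1 times the chance mean. These intervals cover counting error only. With replicate 2 reduced to its 8862 strongest summits, 3198 replicate 1 summits were shared (36.1%).

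The shared set held nearly all of the strongest replicate 1 sites. Among the 10% of replicate 1 summits with the highest scores, 885 of 886 summits were shared, against 63.9% of the 10% with the lowest (60.7 to 67.0%). In replicate 2, 38.4% of the highest-scoring 10% were shared (37.3 to 39.4%), and the remaining bins of 10% lay between 3.95% and 10.8%. Across the 7720 shared sites, the ranks of the 2 scores had a Spearman's rho of 0.767. This correlation runs across sites, which are not independent replicates.

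**Figure D1:**
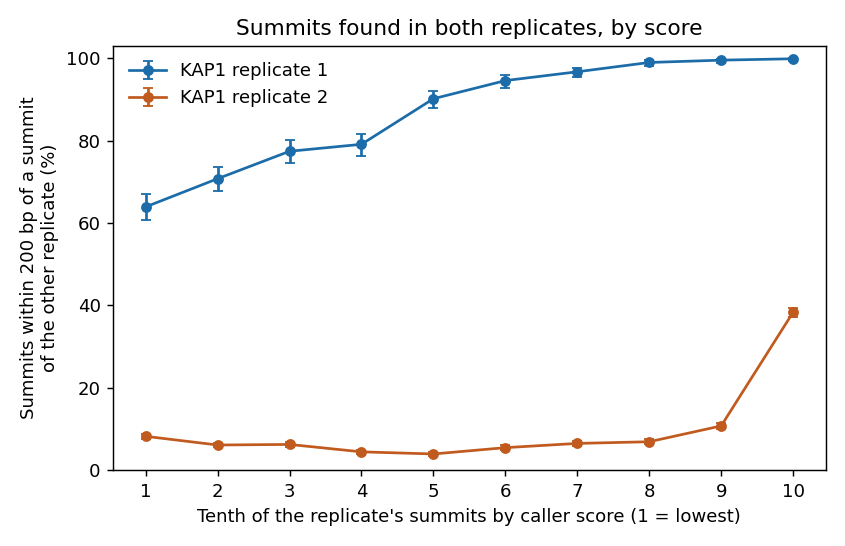
Percentage of summits shared with the other replicate (y axis) by bins of 10% of each list ranked by the authors' score (x axis, lowest to highest), for replicate 1 and replicate 2, with bars for the Wilson 95% interval. The replicate 1 share runs from 63.9% in the lowest bin to 99.9% in the highest, and the replicate 2 share reaches 38.4% in its highest bin.

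The 10 shared sites that ranked highest in both lists lay by Mrps2, Ncoa4, Crlf3, Bcas1, Cfap54, Ino80d, Ubl3, Rex1bd, Rara and Tatdn2, each being the nearest coding gene (coordinates are mm10). The summit at position 28464131 of chromosome 2 had the highest score of both lists, 146.6 in replicate 1 and 153.6 in replicate 2. It lay outside Mrps2, a mitochondrial ribosomal protein gene, at 1820 bp from its nearer end. The summit at position 32159572 of chromosome 14 lay 307 bp outside Ncoa4, the cargo receptor for ferritin breakdown, with scores of 136.6 and 145.4. On chromosome 11, the summit at position 98975562 lay 620 bp outside Rara, which encodes a retinoic acid receptor, with scores of 95.9 and 95.7. The Ino80d, Rex1bd and Tatdn2 summits lay 68, 44 and 206 bp outside their genes. The Cfap54 summit was the only one of the 10 inside its gene, 12680 bp from the nearer end, and the Bcas1 summit was the farthest from its gene at 24535 bp.

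Where KAP1 sat relative to genes was compared with random positions on the same chromosomes. Shared summits were concentrated at the ends of protein-coding genes and were depleted outside them. Of the 7709 shared summits on the numbered and sex chromosomes, 22.6% lay within 1 kb of either end of a coding gene, against 3.23% of random positions (SD 0.204 over 1000 draws), a 6.98-fold difference. Gene bodies held 43.5%, against 39.2% of random positions (1.11-fold), and 33.9% lay outside coding genes, against 57.6% (0.589-fold). Each of these shares lay outside all 1000 draws. Random positions could fall in runs of unknown bases. How much of the small gene body difference rests on this was not tested. The end share was 22.2% for all replicate 1 summits (6.85-fold) and 6.27% for all replicate 2 summits (2.02-fold). With gene ends widened to 2500 bp, the gene body share was no longer above chance (1.01-fold). Gene starts and stops, exons and introns could not be separated, because the gene table used gives only the lowest and highest coordinate of a gene.

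Among coding genes, 1875 of 21900 (8.56%) had a shared summit at an end. The share was 9.42% with all replicate 1 summits and 22.2% with all replicate 2 summits. In gene bodies, 2399 of 19301 genes (12.4%) had one, against 13.3% with replicate 1 and 54.4% with replicate 2.

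Which groups of genes carried KAP1 at their ends was tested for 16 lists fixed before the data were examined, by Fisher's exact test (two-sided) against all other coding genes with Benjamini-Hochberg adjustment. T cell identity genes, regulatory T cell signature genes and ribosomal protein genes had shared summits at their ends at a higher rate than other genes, and olfactory receptor genes at a lower rate. Of the 40 regulatory T cell signature genes, 10 were bound at an end (25%, Wilson 95% interval 14.2 to 40.2%), against 8.53% of other genes (odds ratio 3.57, 95% interval 1.74 to 7.32, exact test adjusted p = 0.00642). The list's share was above that of other genes in replicate 1 (27.5% against 9.39%) and in replicate 2 (32.5% against 22.2%). Using all replicate 2 summits alone, the odds ratio was 1.69 and the exact test's adjusted p was 0.255. With replicate 2 reduced to the length of replicate 1, the ratio was 3.56 and the adjusted p 0.0988, and with a shared distance of 50 bp these were 2.88 and 0.0506.

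Il2ra, which encodes the alpha chain of the high-affinity interleukin-2 receptor, had the strongest end summit of the regulatory T cell list. It lay at position 11642786 of chromosome 2, 6 bp outside the gene, with scores of 58.3 in replicate 1 and 78.3 in replicate 2. Within 20 kb of Il2ra there were 5 shared summits. Lag3, which encodes an inhibitory receptor for MHC class II, had a shared summit inside the gene at 298 bp from its higher end, with scores of 13.4 and 23.7. Rgs1, a regulator of G protein signalling, had one 14 bp outside its higher end (13.2 and 16.2). Capg, an actin-capping protein gene, had one 683 bp inside its lower end (13.2 and 11.2). Ctla4, which encodes an inhibitory receptor that binds the B7 ligands, had a shared summit at position 60909143 of chromosome 1, 118 bp inside the gene. Its score was among the lowest of replicate 1 (2.74) and near the median of replicate 2 (9.08).

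Ikzf2, which encodes the transcription factor Helios, had no shared summit at an end and 1 in its body, at position 69537280 of chromosome 1 (scores 5.56 and 9.15). A replicate 1 summit 238 bp inside its higher end had no replicate 2 partner. Foxp3, the gene of the lineage-defining transcription factor, had no summit of either replicate at an end or in its body. At positions 7572438 and 7565451 of chromosome X, 7238 and 14225 bp below its lower end, it had 2 shared summits. Their replicate 1 scores were 6.64 and 6.16, and their replicate 2 scores were 21.7 and 10.3. Foxp3 lies on chromosome X, where 2.48% of 966 coding genes had a shared end summit, against 8.94% on the numbered chromosomes. Trim28, which encodes KAP1 itself, and Slc1a5, a neutral amino acid transporter gene, had no shared summit within 20 kb. Each had 5 summits of replicate 2 alone in that span.

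**Figure D2:**
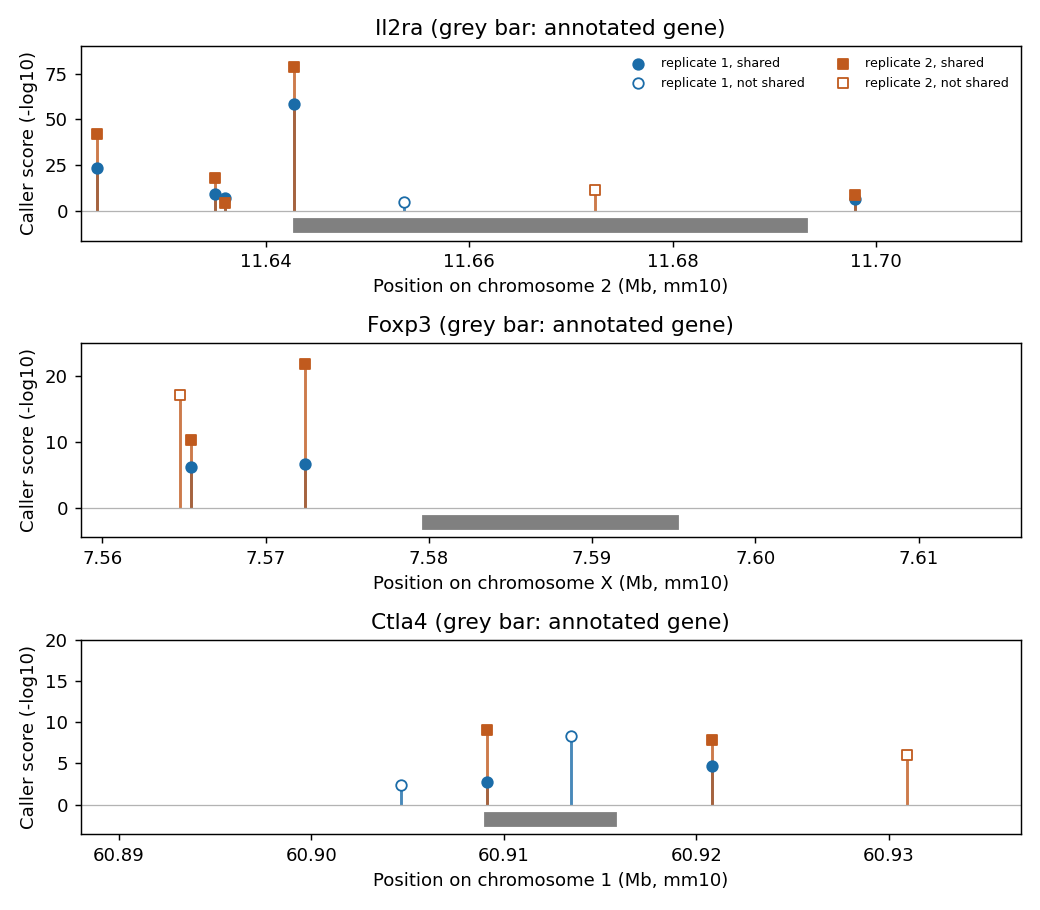
Summits from 20 kb below to 20 kb above Il2ra, Foxp3 and Ctla4, by position in Mb (x axis, mm10) and by the authors' score, the −log10 of a p-value or q-value (y axis), with circles for replicate 1, squares for replicate 2, filled symbols for shared summits, open symbols for summits of 1 list alone and a grey bar for the gene. The Il2ra summit 6 bp outside the gene reaches 58.3 and 78.3, while Foxp3 has no summit at its ends or in its body.

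The T cell identity list, which holds T cell receptor components, their signalling proteins and T lineage transcription factors, had 9 of 26 genes bound at an end (34.6%, 19.4 to 53.8%). The odds ratio was 5.68 (2.53 to 12.8, exact test adjusted p = 0.00105), and 13 of its genes were bound with either replicate's own list (odds ratio 9.67 with replicate 1 alone and 3.51 with replicate 2 alone). The strongest was Cbfb, the partner subunit of Runx transcription factors, whose shared summit lay at position 105170428 of chromosome 8, 246 bp outside the gene (27.7 and 82.6). Cd28, the costimulatory receptor gene, had one 70 bp outside its lower end (15.9 and 27.5). Ptprc, the gene of the CD45 phosphatase, had one 272 bp inside its higher end (10.3 and 19.8), and Cd6, a T cell surface receptor gene, had one 102 bp inside its higher end (10.7 and 8.74). With scores at or above the medians of both lists, the list had an odds ratio of 3.46 and an exact test adjusted p of 0.103. With replicate 2 reduced to the length of replicate 1, these were 3.24 and 0.249.

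Ribosomal protein genes were bound at an end in 21 of 72 cases (29.2%, 19.9 to 40.5%; odds ratio 4.44, exact test adjusted p = 2.95e-06; 2.82 with replicate 2 alone). Rpl5 had a shared summit 73 bp outside its lower end (27.7 and 63.6), Rpl41 one 204 bp outside its higher end (26.8 and 43.9), Rpl28 one 732 bp outside its lower end (29.6 and 27.3) and Rps10 one 390 bp outside its higher end (26.7 and 40.3). Olfactory receptor genes, which are used in sensory neurons, were bound in 2 of 1106 cases (0.181%), against 9.01% of other genes (odds ratio 0.0183, exact test adjusted p = 1.46e-39). These were Olfr525 and Olfr70. With replicate 2 alone, 38 were bound (3.44% against 23.2%, odds ratio 0.118).

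Genes of conventional T cells were bound at an end in 5 of 24 cases (20.8%), which did not pass the exact test after adjustment (adjusted p = 0.113), but passed with scores at or above the medians (odds ratio 5.01, adjusted p = 0.0239). They included Bach2, a transcriptional repressor gene of naive T cells, whose shared summit lay 643 bp outside its higher end (31.0 and 33.7), as well as Igfbp4, Themis and Tbx21. Tbx21 encodes T-bet, the transcription factor of type 1 helper cells. Cell cycle genes were bound in 7 of 32 cases (21.9%, exact test adjusted p = 0.0534), with E2f2, Mcm2, Cdkn1a and Cdk2 ranking highest. They passed the exact test with replicate 1 alone (adjusted p = 0.00696), replicate 2 alone (0.0276), scores at or above the medians (0.0239) and ends of 2500 bp (0.0351). Amino acid transport and mTORC1 genes were bound in 4 of 24 cases (16.7%, exact test adjusted p = 0.257). These were Slc3a2, the heavy chain of several amino acid transporters, with scores of 38.3 and 53.6 at its end summit, and the mTORC1 genes Rptor, Mlst8 and Rheb.

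Partners of KAP1 in silencing were bound at an end in 2 of 21 cases (9.52%, exact test adjusted p = 0.861). These were Setdb1, a histone H3 lysine 9 methyltransferase gene, and Atf7ip, the gene of its cofactor. Imprinted genes were bound in 2 of 38 cases (5.26%, against 5.23% of all other genes of any type; exact test adjusted p = 1), namely Inpp5f (38.5 and 62.2) and Trappc9 (5.10 and 3.52). Markers of other cell types showed few end summits, but these lists are short. None of 12 B cell markers, 14 myeloid markers or 20 neuronal genes was bound, and 1 of 11 erythroid markers was, Tfrc, the transferrin receptor gene (16.7 and 26.3). None of these 4 lists passed the exact test (adjusted p = 0.834, 0.834, 0.655 and 1). Lists of the same gene lengths held means of only 1.18, 1.12, 1.84 and 0.734 bound genes. The B cell, myeloid and neuronal lists already had 0 bound, so the exact test could not have called them lower. Histone genes were bound in 6 of 67 cases (8.96%, exact test adjusted p = 0.945), led by H1f8, H2bc4, H4c11 and H1f5. Histone genes are short, and random lists of the same gene lengths, a comparison added after the data were seen, held a mean of 1.40 bound genes, with this list at percentile 99.8. That place was lost with scores at or above the medians (percentile 65.4), replicate 2 reduced (73.0) and ends of 500 bp (82.7), and histone genes lie in clusters, so that the 6 bound genes rest on 5 summits. Most olfactory receptor genes are short as well and were rarely bound, so they are drawn into these random lists and lower the mean of 1.40. None of 39 Hox genes was bound (exact test adjusted p = 0.152; 0.0198 with ends of 2500 bp), against 11 with replicate 2 alone. Hox genes also lie in clusters, so they are not separate observations.

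**Figure D3:**
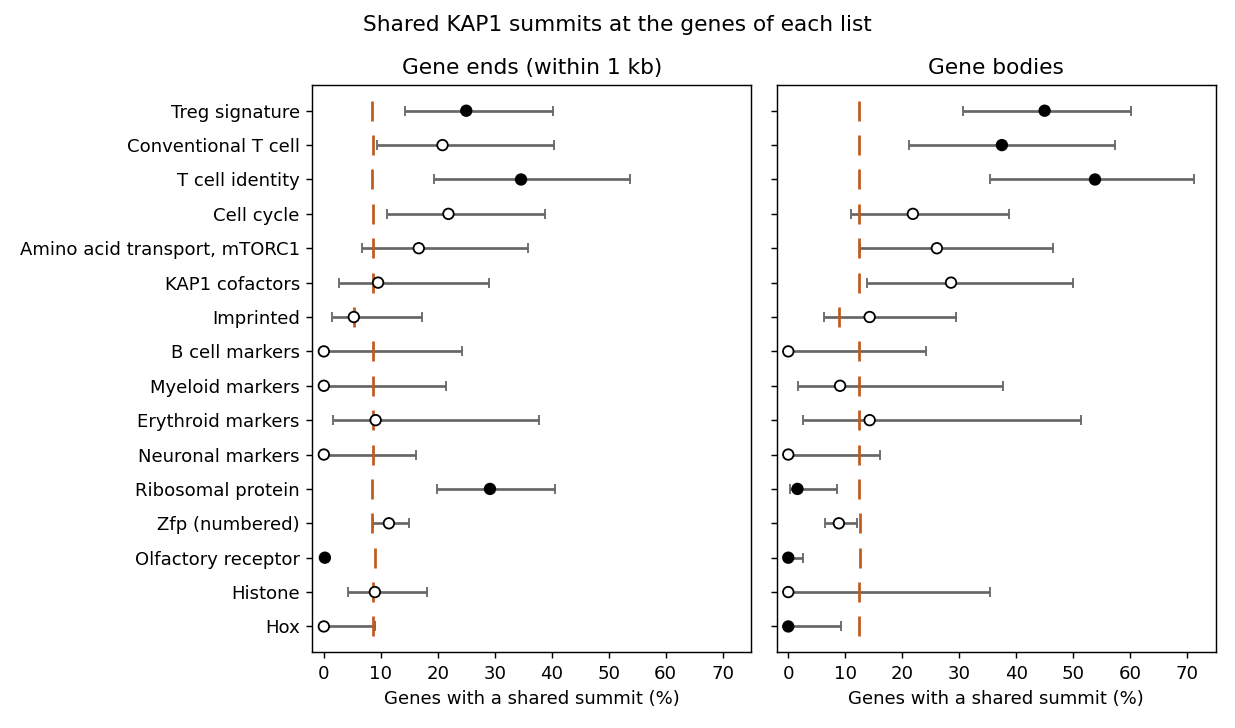
Percentage of each list's genes with a shared summit within 1 kb of an end (left) and in the body (right), with dots filled where the adjusted p of Fisher's exact test was under 0.05, bars for the Wilson 95% interval and orange ticks for the share of the other genes. Regulatory T cell signature genes reach 25% at ends and 45% in bodies, and olfactory receptor genes 0.181% at ends.

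In gene bodies, the 3 T cell lists were bound at a higher rate than other genes. Of the 40 regulatory T cell signature genes, 18 held a shared summit in the body (45%, 30.7 to 60.2%), against 12.4% of other genes (odds ratio 5.80, 3.11 to 10.8, exact test adjusted p = 2.41e-06). None of 10000 random lists matched on gene length was as high, and their mean was 4.61 bound genes. Chosen after their values were seen, Stat5b, which encodes the transcription factor downstream of the interleukin-2 receptor, and Tnfrsf9, a costimulatory receptor gene, held 4 shared body summits each. Prdm1, the gene of the repressor Blimp-1, and Nrp1, the neuropilin-1 gene, held 3 each. T cell identity genes were bound in 14 of 26 cases (53.8%; odds ratio 8.26, exact test adjusted p = 2.41e-06), and conventional T cell genes in 9 of 24 (37.5%; odds ratio 4.24, exact test adjusted p = 0.00631). Using all replicate 2 summits alone, the odds ratio was 1.40 for the regulatory T cell list and 1.40 for the conventional T cell list (exact test adjusted p = 0.609 and 0.751), while it was 4.63 for T cell identity genes (0.00949), and with replicate 2 reduced the conventional list had 3.07 (adjusted p = 0.128).

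Olfactory receptor genes (0 of 149), Hox genes (0 of 38) and ribosomal protein genes (1 of 62) were bound in the body at a lower rate than other genes (exact test adjusted p = 7.25e-08, 0.031 and 0.0182). Ribosomal protein genes are short, and lists of the same gene lengths held a mean of 1.02 bound genes. The matching mean was 1.32 for Hox genes, whose 0 lay at percentile 12.5 of such lists, and 5.50 for olfactory receptor genes, whose 0 lay at percentile 0.185. Hox and olfactory receptor genes lie in clusters, which neither comparison takes into account. With replicate 2 reduced, neither Hox genes (exact test adjusted p = 0.304) nor ribosomal protein genes (0.0866) passed, and Hox genes also did not pass at 50 bp (0.0514) or with scores at or above the medians (0.206). The lists that did not pass the exact test were cell cycle genes (7 of 32, adjusted p = 0.173), amino acid transport and mTORC1 genes (6 of 23, 0.102), KAP1 partners (6 of 21, 0.0762) and imprinted genes (5 of 35, 0.312). The same held for B cell (0 of 12, 0.471), myeloid (1 of 11, 1), erythroid (1 of 7, 0.692) and neuronal genes (0 of 20, 0.238), and for histone genes (0 of 7, 1). Among length-matched lists, however, cell cycle genes lay at percentile 99.0 and neuronal genes at percentile 1.44, both outside the central 95%. Neither place held with scores at or above the medians (percentiles 93.5 and 6.02) or with replicate 2 alone (79.3 and 6.09), where the cell cycle odds ratio was 0.839. Amino acid transport and mTORC1 genes passed the exact test with replicate 1 alone (odds ratio 4.22, adjusted p = 0.00666) and with replicate 2 reduced (4.27, 0.0456), and imprinted genes with replicate 2 alone (2.87, 0.0103). Imprinted genes then lay at percentile 93.3 of length-matched lists, inside the central 95%. With 5000 bp added on both sides, cell cycle (adjusted p = 0.00185), amino acid transport and mTORC1 (0.0483) and neuronal genes (0.0246, lower) passed the exact test. The amino acid transport and mTORC1 list lay inside the central 95% of length-matched lists there, at percentile 95.7. Ribosomal protein genes turned from lower to higher with this span (odds ratio 2.53, exact test adjusted p = 0.000556).

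Zinc finger genes named Zfp with a number were examined because KRAB zinc finger proteins recruit KAP1 and because KAP1 is known to occupy the 3′ parts of such genes. They were planned as the positive control for the antibody. The list was defined by name alone, so it need not hold only KRAB zinc finger genes. Zfp genes were bound at an end in 45 of 394 cases (11.4%, 8.65 to 14.9%), against 8.51% of other genes (odds ratio 1.39, 1.01 to 1.90), which did not pass the exact test after adjustment (adjusted p = 0.113). Among length-matched lists at ends, a comparison added after the data were seen, they lay at percentile 80.2. In the body, 35 of 394 held a shared summit (8.88%), against 12.5% of other genes (odds ratio 0.682, 0.481 to 0.968, exact test adjusted p = 0.0698). Their ends held 29.2 summits per Mb, against 25 for other genes, and their bodies held 3.33 against 3.42. An end summit lay at the lower coordinate in 26 Zfp genes and at the higher coordinate in 19. The last exon could not be examined, because strand and exons are absent from the gene table used, so the positive control was not run as planned. The parts that were run gave no higher rate that passed in the main setting. The strongest were Zfp438 (35.8 and 62.0), Zfp64 (33.1 and 56.7), Zfp809 (28.0 and 59.9) and Zfp101 (23.1 and 48.0). Zfp809 encodes a protein that recruits KAP1 to silence retroviral DNA, and it had 2 shared summits within 1 kb of its ends. With gene ends widened to 2500 bp, the end odds ratio was 1.61 (exact test adjusted p = 0.0022), and with summits at or above the median scores the body odds ratio was 0.435 (0.0032). With 5000 bp added on both sides of the gene, the body odds ratio was 1.17 (exact test adjusted p = 0.284).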

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

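No paired analysis was possible because the input samples, which share replicate numbers 1 and 2 with the KAP1 samples, have no summit list of their own, so no result compares the groups. Read depth is unknown and limits the comparison of the lists. Not run, for lack of sequence, strand and exons, were random positions and lists matched on GC content, the last part of zinc finger genes, and the motif alternatives with their windows and backgrounds. Restricting summits to the numbered chromosomes and X left the direction and call of all 32 list tests as they were. A distance of 500 bp also left every call, and turned the direction of imprinted genes at ends alone (odds ratio 0.999 against 1.01).

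The number of shared summits was 4271 with scores at or above the median of each list and 3198 with replicate 2 reduced to the length of replicate 1, both of which use fewer summits. These were 89.4% of the 4777 replicate 1 summits kept and 36.1% of all 8862, against 87.1% in the main setting. It was 7153 at 50 bp and 7858 at 500 bp. At 50 bp, 97.1% of the highest-scoring and 51.3% of the lowest-scoring 10% of replicate 1 were shared, and at 500 bp 67.3% of the lowest-scoring 10%. The count stayed between 26.8 and 236.5 times chance. Gene ends stayed enriched under every location setting run, from 2.02-fold with all replicate 2 summits to 9.07-fold with ends of 500 bp. With ends of 2500 bp, gene bodies were 1.01-fold, no longer above chance (the cause was not tested). With each replicate's own list, the fold ranged from 2.02 to 6.85 at ends, from 1.11 to 1.2 in bodies and from 0.595 to 0.815 outside genes.

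For regulatory T cell genes at ends, Fisher's exact test gave an odds ratio of 2.88 (adjusted p = 0.0506) at 50 bp and 3.56 (adjusted p = 0.0988) with replicate 2 reduced, where fewer genes were bound. With each replicate's own list it ranged from 1.69 to 3.66 (exact test adjusted p = 0.255 with replicate 2 alone). In bodies it ranged from 1.40 (exact test adjusted p = 0.609, replicate 2 alone) to 6.59. Over the other settings the list kept its call, and its adjusted p ranged from 0.00296 to 0.0443 at ends. For Zfp genes at ends, the odds ratio was 1.61 with ends of 2500 bp (exact test adjusted p = 0.0022) and ranged from 1.34 to 1.38 with each replicate's own list, passing with replicate 2 alone (adjusted p = 0.0194). In bodies it was 0.435 with scores at or above the median, 0.518 with replicate 2 reduced and 0.666 without genes of X, Y and mitochondrial DNA (exact test adjusted p = 0.0032, 0.0461 and 0.0486), an alternative chosen after seeing the data, and it ranged from 0.714 to 0.819 with each replicate's own list. The cause of these changes was not tested.

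At ends, 3 lists were higher and 1 lower. Reducing replicate 2 left 1 higher (ribosomal protein genes), ends of 2500 bp gave 5 higher and 2 lower, and length-matched lists, chosen after seeing the data, gave 5 higher (cell cycle and histone genes were added) and 2 lower (Hox genes were added). The number higher was 4 with either replicate's own list and the number lower was 1. In bodies, 3 lists were higher and 3 lower. Adding 5000 bp on both sides gave 6 higher, and it turned ribosomal protein genes from lower to higher (odds ratio 2.53, exact test adjusted p = 0.000556), since that span takes in the gene ends. It also turned the Zfp body odds ratio to 1.17 (exact test adjusted p = 0.284). Length-matched lists gave 4 higher in bodies, with cell cycle genes added, and 2 lower, with neuronal genes added and ribosomal protein and Hox genes lost. With each replicate's own list, 2 to 4 lists were higher in bodies and 3 lower. Of 54 named genes, 15 changed their number of end summits with ends of 500 bp, 15 with replicate 2 reduced, 8 with scores at or above the median and at most 2 under any other setting.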

Other observations

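All tests in this part were chosen after the result they bear on had been seen. Among 11 gene lists added in this way, tRNA genes and genes of the mitochondrial ribosome had shared summits at their ends at a higher rate than other genes. Of 430 tRNA genes, 83 were bound (19.3%), at 56 distinct summits, against 5.11% of all other genes (odds ratio 4.44, Fisher's exact test with Benjamini-Hochberg adjustment over the 11 lists, adjusted p = 4.83e-24). The share was 22.6% with replicate 1, against 5.61% of other genes, and 31.6% with replicate 2, against 16.8% (odds ratios 4.90 and 2.29). The 83 include 8 tRNA genes of mitochondrial DNA. Without that DNA, 75 of 408 were bound (18.4% against 5.10%, odds ratio 4.19, exact test p = 1.38e-21). Many tRNA genes lie close together, so 1 summit can count for several. Genes annotated as small nuclear RNAs were bound in 26 of 1004 cases (2.59%, against 5.29%; exact test adjusted p = 0.000114), although lists of the same gene lengths had a mean of 33.5 bound genes, with this list at percentile 6.78. Of 78 mitochondrial ribosomal protein genes, 20 were bound (25.6%; odds ratio 3.71, exact test adjusted p = 2.31e-05). Interleukin receptor genes were bound in 8 of 41 cases (odds ratio 2.60, exact test adjusted p = 0.0389), at 7 distinct summits, but lay at percentile 96.8 of length-matched lists, inside their central 95%. They did not pass with replicate 1 alone (exact test adjusted p = 0.0961) or replicate 2 alone (0.121). The bound members include Il2ra, Il7r, Il4ra and Il1rl1. Il1rl1 encodes the interleukin-33 receptor. Its end summit had the same mean percentile rank (56.6) as that of Il18r1, also bound, so 1 summit may count for both. At their ends, genes of the NF-kappaB pathway (3 of 18), TNF receptors (2 of 20), chemokine receptors (1 of 16), MHC molecules (2 of 38) and keratins (1 of 49) did not pass the exact test (adjusted p = 0.269, 0.84, 1, 0.846 and 0.195). In bodies, NF-kappaB pathway genes did (6 of 18, exact test adjusted p = 0.0496), among them Nfkb1 with 3 shared summits. MHC (0 of 38), clustered protocadherin (0 of 57) and vomeronasal receptor genes (0 of 144) were lower in bodies (exact test adjusted p = 0.0427, 0.00497 and 7.41e-08), with MHC genes at percentile 13 of length-matched lists. Clustered protocadherin genes, which give neurons their surface identity, were bound at an end in 0 of 57 cases (exact test adjusted p = 0.0313), but in 6 with replicate 2 alone (10.5% against 22.2%, exact test adjusted p = 0.0673), and vomeronasal receptor genes were bound in 1 of 353 (exact test adjusted p = 4.66e-12). Protocadherin, MHC and vomeronasal receptor genes of these lists lie in clusters, so the exact test counts neighbouring genes as if they were separate observations.

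The coding genes with the most shared summits from 20 kb below to 20 kb above the gene were Akap13 and Prkch, with 12 each. Maml3, a coactivator of Notch signalling, had 10. Prkch encodes a protein kinase C isoform used in T cells. Clec16a, Fnbp1, Rere and Ryr1 had 9 each. Akap13 spans 299084 bp and Maml3 418000 bp, and longer genes hold more summits by chance. Histone genes had the highest fold of the 25 lists counted in this span, 4.59 times the mean of length-matched lists, and 2.46 times with replicate 2 alone. With replicate 1 alone they had 4.24 times, below T cell identity genes (4.89 times). Histone genes lie in clusters, so 1 summit can count for several, which matching on length leaves out. Their fold also rests on a low matched mean of 0.166 summits per gene. Short genes include most olfactory receptor genes, which had 0.0217 per gene and are drawn into the matched lists. Histone genes themselves had 0.761 summits per gene, below T cell identity genes (2.42). Cell cycle genes (2.29 times), conventional T cell genes (2.48 times) and KAP1 partners (2.07 times) were also higher (permutation test over length-matched lists, adjusted p = 0.00167, 0.0035 and 0.0279). With replicate 2 alone, cell cycle genes (1.26 times, adjusted p = 0.164) and conventional T cell genes (1.14 times, 0.488) did not pass this permutation test, and KAP1 partners had 1.43 times (0.0445). No Hox gene and no clustered protocadherin gene had a shared summit in this span (0 of 39 and 0 of 57 genes). Genes of both lists lie in clusters and share much of this span, so they are not separate observations. With replicate 2 alone, Hox genes had 2.72 summits per gene, 1.17 times the mean of length-matched lists.

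Genes of regulatory T cells had 1.83 shared summits per gene within 20 kb, 3.18 times the mean of lists of the same gene lengths, and T cell identity genes had 2.42, which is 3.91 times. None of 10000 length-matched lists was as high as either, and 25 of the 26 T cell identity genes had at least 1 such summit. The tables argue against an equal spread over all gene types, because neuronal genes had 0.161 times the summits of length-matched lists, with 2 of 20 genes having any. Markers of other cell types were not all lower, with 1.16 times for B cell, 2.36 times for erythroid and 0.291 times for myeloid markers. The erythroid value rests largely on Tfrc, which had 6 shared summits in this span, and 4 of the 11 erythroid genes had any. None of these marker lists passed the permutation test. With replicate 2 alone, neuronal genes had 0.802 times and did not pass (permutation test over length-matched lists, adjusted p = 0.349), and the T cell folds were 1.40 and 1.48. Ribosomal protein genes, in use in every cell, were also higher (2.42 times). KAP1 at T cell genes therefore cannot be told apart from chromatin that is open in these cells and recovered with any antibody. The input samples were not analysed here, and they were made without antibody, so they could not show what any antibody recovers. A candidate explanation is that KAP1 occupies regulatory elements of genes used in these cells, which was not tested here.

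Few summits lay on chromosome X. Shared summits numbered 0.398 per Mb there, against 1.88 to 5.71 on the numbered chromosomes, and all 68 replicate 1 summits of X were shared. Sequence outside coding genes was low as well, where the density of replicate 2 summits on X was 0.0696 times that of the numbered chromosomes (95% interval 0.0608 to 0.0793). This cannot decide whether less use of X genes is the whole cause, because summits outside coding genes may also depend on gene use. A lower depth on X under a fixed threshold, as a single X copy could give, stays open. Doubling a score cut served as a rough stand-in for less depth. The cut was the upper edge of the lowest-scoring bin of each list, because the calling threshold is not given. In replicate 1, going from 3.45 to 6.90 lowered the share of autosomal genes bound at an end from 8.87% to 5.71%. That was still above the 2.48% of X genes at the lower cut. In replicate 2, going from 5.64 to 11.3 lowered the autosomal share from 20.8% to 9.21%, against 4.97% of X genes at the lower cut. Depth is unknown, the labels give no sex of the mice, and beyond the use of X genes no biological explanation was tested.

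Most replicate 2 summits had no partner in replicate 1, and 32602 of the 79515 (41.0%) carried 1 of 13 score values that each recurred at least 500 times. Recurring scores are not particular to replicate 2, which had 4942 distinct values, while the 8862 replicate 1 summits had 650. Of the replicate 2 summits with 1 of these 13 recurring scores, 1.72% were shared, against 15.3% of the others. Over all summits with a recurring score, 2.91% lay at gene ends, against 3.04% of random positions (SD 0.0938), or 0.960 times. Leaving out the shared ones lowered this share to 2.63%, or 0.866 times. The summits with a recurring score thus lay at gene ends about as often as random positions, and background calls cannot be told apart from true sites away from genes. They are part of every setting that used all replicate 2 summits alone. Of the other unshared summits, 6.05% lay at gene ends, against 3.14% of random positions and outside all 1000 draws, or 1.93 times. This argues against background spread evenly over the genome as the source of all of them. It cannot speak to background raised in open chromatin, because the input samples were not analysed here. A greater depth or a looser threshold in replicate 2 may add weaker true sites, which was not tested, and no biological explanation was tested.

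The strongest unshared summit of replicate 2 lay at position 40308119 of chromosome 18, with a score of 82.2, at 51814 bp from Kctd16. The strongest unshared summit of replicate 1 had a score of 16.3 and lay at position 21940874 of chromosome 13, 228 bp from a replicate 2 summit.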
